A study of Drosophila melanogaster with 6 samples.

How the data were processed

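RNA was measured in 6 libraries of Drosophila melanogaster heads, 3 from Prp31 mutant flies and 3 from white control flies, aged 2 days, with 50 heads pooled per library. Per the labels' protocols, poly(A) RNA was enriched and turned into strand-specific libraries with 15 cycles of PCR, and sequenced as 75 base single reads on 1 lane. The deposited values are FPKM per gene and library, made by the authors, with replicates not pooled. Per the submitters' processing notes, CASAVA 1.8 and STAR 2.5.2b were used with the genome build BDGP6. The tool that computed FPKM, the annotation release, the handling of strand and of reads that fit several places, and any filter on genes are not given in the sources used here. FPKM divides by gene length and library total, so a few very abundant transcripts that differ between libraries lower all others. The top 10 genes held 15.9% to 22.2% of the column total.

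Groups were taken from the sample labels, and each column was matched to its sample by title. The table holds 11836 genes. Of these, 11630 identifiers were found in the reference annotation of the same assembly name, 116 more were placed by symbol, and 90 had no position. Positions are those of that annotation, counted from 1. No FASTA was used here, so GC content was not analysed.

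The comparison was mutant against control. Because FPKM are not counts, no count model was used. Genes with a mean of at least 1 FPKM over the 6 libraries were kept, log2(FPKM + 1) was taken, and limma 3.58.1 in R 4.3.3 was fitted with a variance trend, with Benjamini-Hochberg adjustment over the 8465 genes and a threshold of 0.05. Gene lists were tested with camera of limma at its preset correlation of 0.01, adjusted over the 25 lists with at least 5 tested members, and beside it with camera at an estimated correlation and with fry. Called genes per chromosome arm, and within 2 Mb of Prp31 against the rest of 3L, were tested with Fisher's exact test, two-sided.

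The named genes followed a rule. It took Prp31, and the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap. From each list it took up to 4 called members by size of change, or the 2 most abundant where none was called, and it took the 4 most abundant genes of each marker list of another tissue or sex. Other genes named in the text complete a count, or were chosen after their values were seen: ninaE, Rh2, Rh3, Rh5, pinta, rdhB, cd, TotA, CecA1, AttC, Drsl2, Drsl4, GNBP1, Rel, GstD1, Cyp309a1, hid, skl and egr, besides those in the closing section. The 25 fixed lists held 740 symbols, of which 67 had no match in the table, and 10 genes were in more than 1 fixed list. The tri-snRNP list also holds CG10754, whose product belongs to the SF3a complex. The 4 further lists followed rules: ribosomal proteins, mitochondrial genome, intronless genes, and genes with 10 or more introns. The design, the lists, the rule and the alternatives other than those named below as added were set before the data were examined.

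The limma step was tested on simulated values for the 8465 genes of this comparison, with the real means and residual spreads and 200 changed genes in each of 5 runs. It recovered 53.2%, 87.6%, 96.8% and 100% of changes of 0.5, 1, 2 and 4 in log2, with 41 false calls in all. Camera called a planted list of 30 genes shifted by 0.5 in 5 of 5 runs and 0 of 125 other list tests. Both simulations drew genes as uncorrelated, with equal spread in all libraries. A library that differs in many genes at once, as white control replicate 3 does, was not simulated, so false calls may be more frequent in these data.

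The alternatives set then were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, median-ratio scaling, quantile normalization, no variance trend, a robust prior, library weights, the replicate number as a block, each library left out in turn, and windows of 1 and 5 Mb around Prp31. A covariate of yolk protein transcripts, the counts of list members and of gene families with each library left out or with another scaling, and the same for the genes chosen after their values were seen, were added after seeing the data. The covariate was the mean log2 value of Yp1, Yp2 and Yp3 in each library. The replicate numbers were not used as pairs, since the labels give them no meaning.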

Results

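Messenger RNA was measured in adult Drosophila melanogaster heads by strand-specific, poly(A)-selected RNA sequencing. Prp31 encodes a splicing factor of the U4/U6.U5 tri-snRNP, and mutations in its human counterpart cause a dominant hereditary degeneration of the retina, which the study set out to model in the fly. The samples were 3 libraries from flies homozygous for the Prp31 mutation P18 and 3 libraries from control flies described as white, a genotype named after the eye colour gene w. Each library came from 50 pooled heads of flies aged 2 days, kept at 25 °C, and the series covers males and females. The values were FPKM for 11836 genes, with column totals between 348791 and 402452 FPKM. Reads per library were given only as an average, so exact depths are not known, and counting errors per gene were not computed. In the low values, 1 read was estimated to be worth 0.957 to 1.09 times as much as in mutant replicate 1. The estimate searched only ratios near 1, so it could not have shown a large difference, and relative depths stay unknown. Whether the replicates came from separate cultures is not stated, so the p-values measure only the spread between these samples, which may be technical.

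The mutated gene itself was present at the control level. Prp31 (FBgn0036487, 3L, 15159100 to 15161138, build BDGP6) had 13.76 ± 0.362 FPKM in mutant heads and 13.95 ± 0.113 FPKM in control heads (mean ± SD, n = 3 each). The log2 fold change was -0.02 with a standard error of 0.06 (limma, adjusted p = 0.872). The labels do not say what the mutation alters in the transcript, so this level does not check them, and 263 bases of the gene overlap CG7011 on the opposite strand. Across the 8465 genes with a mean of at least 1 FPKM, 299 were higher and 661 lower in mutant heads at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 243 of these differed at least 2-fold. With each library rescaled by its median ratio the split was 360 higher and 454 lower, and with quantile normalization it was 384 and 467, as the median log2 fold change of all genes was -0.066 before and 0 after. In 2644 genes, 31.2% of those tested, the mutant and control libraries did not overlap, where chance gives 10%. White control replicate 3 stood apart from the other controls. Its log2 values correlated at 0.990 and 0.988 with those of control replicates 1 and 2, which correlated at 0.997 with each other (Pearson, across genes, which are not independent replicates). Without it 838 genes were higher and 1383 lower, and 954 of the 960 called genes were called again in the same direction. The total of 960 became 532, 647 and 517 without mutant replicates 1, 2 and 3, and 412 and 498 without control replicates 1 and 2.

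The largest increases joined immune and stress peptides, an opsin and enzymes of metabolism. Dro, which encodes the antimicrobial peptide drosocin, had 235 ± 35.5 FPKM in mutant and 6.98 ± 9.36 FPKM in control heads (log2 fold change 5.56, SE 0.71, limma adjusted p = 0.00333). Its highest control value, 17.8 FPKM, was that of control replicate 3. The uncharacterised genes CG30054 and CG32581 were near the floor in controls, at 0.700 ± 0.163 and 0.062 ± 0.0478 FPKM, and reached 69.3 ± 8.56 and 28.8 ± 0.693 FPKM in mutants. AttA, an attacin, rose by a log2 fold change of 3.75, as did the stress peptide gene TotX, also by 3.75. The methyltransferase gene Gnmt rose by 3.74, the odorant binding protein gene Obp57a by 3.70, TotC by 3.67 and the cytochrome P450 gene Cyp6a17 by 3.63. AttA has a near-identical neighbour, AttB, and Cyp6a17 a similar one, Cyp6a23, so the division of reads within each pair is uncertain. All fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes.

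The largest decrease was that of lectin-28C, which encodes a C-type lectin, from 28.6 ± 2.38 to 0.709 ± 0.0632 FPKM (log2 fold change -4.11, SE 0.08, limma adjusted p = 3.74e-07). The gene overlaps TwdlE on the opposite strand over 2164 bases, and whether strand was used in counting is not stated. CG4962, within 2 Mb of Prp31 on 3L, had a log2 fold change of -3.63 and the odorant binding protein gene Obp99d one of -3.12. They were followed by the lysosomal thiol reductase gene GILT3 (-3.05), the cytochrome P450 gene Cyp9f2 (-2.88) and phr, the gene of a DNA photolyase (-2.68). CG33296, Ugt86Dd, CG6908 and CG13704 ended the list of 10, between -2.64 and -2.60. The order depends on the scale: with a pseudocount of 0.1 CG13704 (-5.3), near the floor in mutants, passed lectin-28C (-5.15). All 20 genes with the largest changes stayed past the threshold under every alternative in which they were tested. Sizes moved more for some. Dro went from 5.56 to 3.88 with the yolk protein covariate and to 6.52 without control replicate 3, and Gnmt from 3.74 to 2.47 with that covariate.

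Among the opsins, the light-sensing proteins of photoreceptors, Rh6 and Rh4 rose in mutant heads. Rh6 (FBgn0019940, 3R, 15483158 to 15484699) had 548, 561 and 402 FPKM in the mutant libraries and 21.6, 22.1 and 21.2 FPKM in the controls, a log2 fold change of 4.46 (SE 0.14, limma adjusted p = 3.23e-06). Rh4 had 174 ± 32.8 FPKM against 76.0 ± 2.10 FPKM (log2 fold change 1.17, SE 0.15, limma adjusted p = 0.00288). It lies on the opposite strand to sina over 4962 bases, and within 2 Mb of Prp31 on 3L. ninaE, the most abundant opsin transcript, had 14190 ± 2010 and 10180 ± 1245 FPKM (log2 fold change 0.48, SE 0.38, limma adjusted p = 0.444). Rh5 had a log2 fold change of -0.44 (limma adjusted p = 0.0745), Rh3 one of -0.14 (0.600) and Rh2 one of 0.04 (0.797), and none passed the test. Of the 36 phototransduction genes tested, 3 rose, 3 fell and 30 did not pass; adjusted over the list alone 4 rose and 4 fell. The third that rose was pinta (0.29), a retinoid-binding protein gene, whose call was lost without any 1 library other than control replicate 3 (0.11 to 0.192). The 3 that fell were ninaD (-1.15), which encodes a carotenoid scavenger receptor, laza (-0.65), which encodes a lipid phosphatase, and rdhB (-0.48), a retinol dehydrogenase gene. The call of laza was lost without mutant replicate 1, 2 or 3 or control replicate 2, with adjusted p between 0.0502 and 0.0696, and that of rdhB without control replicate 1 (0.0503). With the yolk protein transcripts as a covariate, an alternative chosen after seeing the data, ninaD (-0.89, adjusted p = 0.0814), laza (0.12) and pinta (0.181) lost their calls, the list had 4 higher and 1 lower, and its median was 0.20 with a camera call as up (1.61e-05). Without control replicate 3 ninaE passed (0.0246), as did Rh5 (0.0447), and the list had 5 higher and 8 lower. The list as a whole was not called (camera adjusted p = 0.24), except under that covariate and without mutant replicate 3 (up, 0.042). With an estimated correlation camera gave an adjusted p of 0.85 in the main comparison, and the exceptions were not retested that way. The median of the list was -0.04, its mean 0.11, and its median with median-ratio scaling 0.03.

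**Figure D1:**
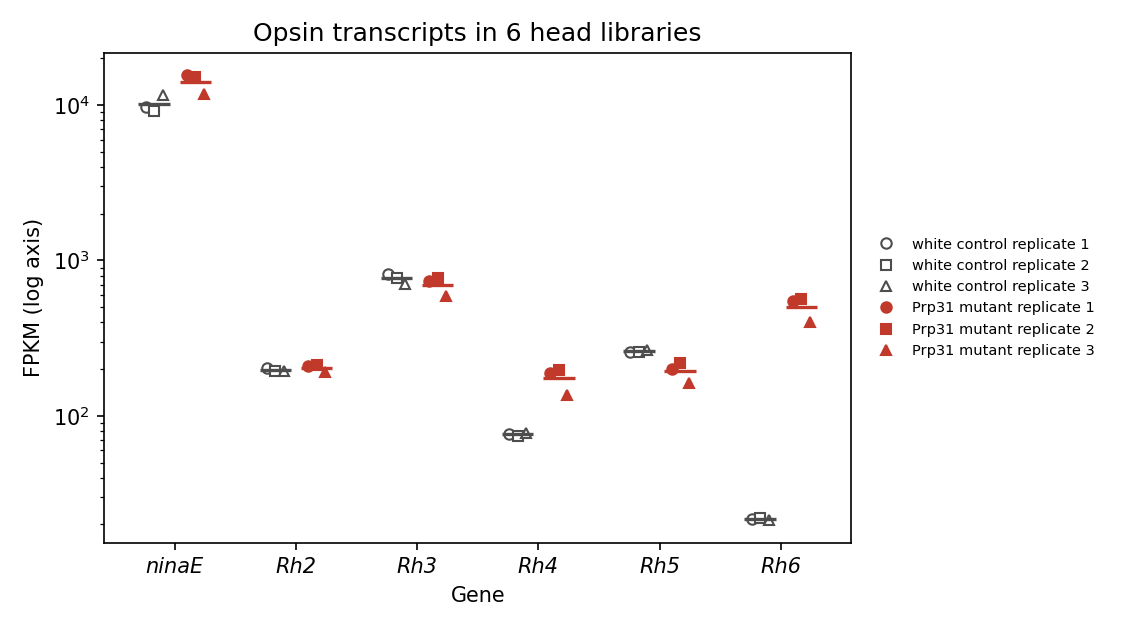
FPKM of the 6 opsin genes (log axis) in each of the 3 white control libraries (open grey symbols) and the 3 Prp31 mutant libraries (filled red symbols), with horizontal bars at the group means. Rh6 lies at 402 to 561 FPKM in mutant and 21.2 to 22.1 FPKM in control libraries, while the values of Rh2 overlap between the groups.

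Of 26 eye pigment genes tested, 5 fell and 0 rose. The pigment precursor transporter gene st fell from 18.2 ± 2.14 to 2.54 ± 0.406 FPKM (log2 fold change -2.44, SE 0.11, limma adjusted p = 2.27e-05). Pu, the GTP cyclohydrolase gene of pteridine synthesis, had a log2 fold change of -1.04, se -0.66 and cd -0.44. The remaining member that fell, Drat (-0.80), is described in the table as a death resistor target with an Adh domain and not by pigment synthesis. Adjusted over the list alone, 5 fell and 0 rose, and at an unadjusted p under 0.05 limma gave 6 lower and 2 higher. Camera did not call the list (adjusted p = 0.47). Fry, which tests whether its genes moved on balance 1 way and not against other genes, gave an adjusted p of 0.024. The median of the list was -0.04 and its mean -0.22, beside a median of -0.066 for all genes. The call of Pu was lost without mutant replicate 1 or 3 or control replicate 1 or 2 (adjusted p 0.0533 to 0.0729), and that of Drat without mutant replicate 1 or 3 or control replicate 1 (0.0575 to 0.0592). se lost its call without control replicate 1 (0.0515), and cd without mutant replicate 1 or 3 or control replicate 1 or 2 (0.0575 to 0.104) and under both other scalings (0.0829 and 0.0845). Without mutant replicate 1 or 3 the list had 2 lower, without control replicates 1 and 2 it had 1 and 3, and without control replicate 3 it had 8 lower and 2 higher. The st gene lies within the span of CG43373 on the opposite strand, with 2810 bases shared. It also lies within 2 Mb of Prp31 (3L, 16497651 to 16500460), so a linked allele cannot be told apart from the mutation. Of 25 genes of photoreceptor structure and fate, melt fell (-0.79) and tantalus, entered under the symbol tan, rose (0.36), with the same counts adjusted over the list alone. tantalus lost its call without mutant replicate 1 or 2 or control replicate 1 or 2 (0.0506 to 0.0929), and without control replicate 3 the list had 4 lower and 2 higher. Camera did not call the list (adjusted p = 0.97).

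Few components of the splicing machinery passed the test. None of 19 tri-snRNP proteins was called by limma, adjusted over all genes or adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05. The most abundant of them were hoip, with 21.1 ± 1.23 and 21.9 ± 5.15 FPKM in mutant and control heads, and CG3436, with 16.9 ± 1.09 and 18.9 ± 0.311 FPKM. Among 34 other core spliceosome proteins SmE alone rose (log2 fold change 0.43), and 0 did when adjusted over the list alone. The call of SmE was lost without any 1 of the libraries other than control replicate 3 (limma adjusted p 0.0663 to 0.111). Without control replicate 3, 6 members of this list were higher and 1 lower. Camera called the list as up (adjusted p = 0.028, median 0.05), which was lost with an adjusted p of 0.85 with an estimated correlation, and without mutant replicate 1 or 3 or control replicate 1 or 2 (0.0566 to 0.158), or with a filter of 5 FPKM (0.0697). SmE shares 521 bases with CG7102 on the same strand. Of 26 SR and hnRNP regulators 1 fell, Doa (-0.39), a kinase of SR proteins, also when adjusted over the list alone; its call was lost without mutant replicate 1 or 3 or control replicate 1 (0.0507 to 0.0934). Camera gave this list an adjusted p of 0.93 and the tri-snRNP proteins one of 0.41. Of 722 intronless genes 38 rose and 58 fell, and of 658 genes with 10 or more introns 10 rose and 27 fell. Adjusted over the list alone these were 43 and 63, and 6 and 16. Adjusted over all genes, 96 of the 722 and 37 of the 658 were called, beside 960 of all 8465 genes tested. The share was thus below that of all genes only in the second list, a difference that was not tested. Camera called neither (adjusted p = 0.24 and 0.25), with medians of -0.03 and -0.10, beside a median of -0.066 for all genes; the first became 0.04 with median-ratio scaling. Without control replicate 3 camera called both, the first as up (adjusted p = 0.0486) and the second as down (0.0173), and the counts were 106 and 103, and 16 and 91. The second was also called as down without mutant replicate 1 (0.00755). With an estimated correlation camera gave adjusted p of 0.85 and 0.9 in the main comparison, and the calls with a library left out were not retested that way. Without any 1 other library the intronless genes called were 55 to 69, lowest without control replicate 1, and those with 10 or more introns 9 to 26, lowest without control replicate 1.

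Of 52 antimicrobial and humoral immune genes 12 rose and 4 fell; adjusted over the list alone 20 rose and 4 fell. Beside Dro, AttA, TotX and TotC, those that rose included TotA (2.11), the cecropin gene CecA1 (2.09) and AttC (1.65). Those that fell were Drsl4 (-2.26), Drsl2 (-0.90), GNBP1 (-0.56) and Rel (-0.60), the gene of the NF-kappaB factor of the Imd pathway. Camera called the list as up (adjusted p = 2.7e-08, median log2 fold change 0.45), and the call was lost with an adjusted p of 0.81 with an estimated correlation. Control replicate 3 lay above control replicates 1 and 2 in this list by a median of 0.66, while the mutants lay above control replicate 3 by a median of 0.09. Under the yolk protein covariate the median was 0.21, 5 members rose and 4 fell, camera gave an adjusted p of 0.0231, and TotA (0.107), CecA1 (0.175), AttC (0.285) and Rel (0.148) lost their calls. Without control replicate 3, 28 members rose and 4 fell, and without mutant replicates 1 and 2 and control replicates 1 and 2 the number that rose was 4, 5, 6 and 6. CecA1 and AttC lost their calls without at least 4 of the libraries taken 1 at a time (up to 0.0716 and 0.108), among them mutant replicates 1 and 2 and control replicates 1 and 2, and AttC also without mutant replicate 3. TotA lost it without mutant replicate 1 (0.0527), and Rel without mutant replicate 1 or 3 or control replicate 2 (0.0578 to 0.0696). None of 15 heat shock proteins was called by limma, also when adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. Camera did not call them (adjusted p = 0.47, median -0.46), but without control replicate 3 it called them as down (0.0281) and 7 members fell. With an estimated correlation camera gave an adjusted p of 0.85 in the main comparison, and calls under the alternatives were not retested that way. The direction was not stable: control replicate 3 differed from the other controls by a median of -0.77, the mutants lay above control replicate 3 by 0.28, and with the yolk protein transcripts as a covariate the median was 0.41 and camera called the list as up (0.0314). Hsc70-4 had 568 ± 44.1 and 520 ± 37.2 FPKM. Of 19 genes of the unfolded protein response 0 passed limma, also when adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05. Camera called them as up (adjusted p = 0.034, median 0.06), lost with an adjusted p of 0.81 with an estimated correlation and without mutant replicate 2 or 3 or control replicate 1 or 2 (0.0626 to 0.112), with quantile normalization (0.0617) or with a filter of 5 FPKM (0.0571), and without control replicate 3 limma called 4 members as higher. Xbp1 had 235 ± 18.8 and 224 ± 9.91 FPKM.

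Detoxification genes changed in both directions. Of 56 tested, 9 rose and 12 fell; adjusted over the list alone 10 rose and 13 fell. Cyp6a17 (3.63), Cyp6a2 (1.93) and GstD1 (1.08) were among those that rose, and Ugt86Dd (-2.62), Cyp6a20 (-2.03) and Cyp309a1 (-1.77) among those that fell. Camera, which asks for a shift in 1 direction, gave an adjusted p of 0.33, and 0.0153 as up without mutant replicate 1. Fry's test of change in either direction gave an adjusted p of 1.4e-06. That test also passed many other lists, such as the intronless and the phototransduction genes (fry, adjusted p = 2e-05 each), so it does not set this list apart. Without mutant replicates 1 and 3 and control replicates 1 and 2 the numbers that fell were 8, 8, 8 and 7. Cyp6a2 shares 1743 bases with Epac on the same strand. Of 16 cell death genes 7 fell and 0 rose, also when adjusted over the list alone, and at an unadjusted p under 0.05 limma gave 8 lower and 0 higher. The largest decreases were those of rpr, an inhibitor of apoptosis inhibitors, with 2.09 ± 0.203 against 4.98 ± 0.799 FPKM (log2 fold change -0.95, SE 0.11, limma adjusted p = 0.00231), and of the initiator caspase gene Dronc (-0.72). Dark, the gene of its adaptor, had -0.56 and the caspase gene Strica -0.55, whose call was lost without mutant replicate 1 (0.0518) or control replicate 2 (0.0706), and under quantile normalization (0.0549). The other three, hid, skl and egr, lost their calls without any 1 library other than control replicate 3 and under both other scalings, where 4 and 3 members fell. Without mutant replicates 1, 2 and 3 and control replicates 1 and 2 the list had 3, 4, 4, 4 and 3 lower. Under the yolk protein covariate 2 fell, and Dark (0.0828), Strica (0.0594), hid (0.34), skl (0.307) and egr (0.231) lost their calls. Camera called the list as down (adjusted p = 0.034, median -0.22). This was lost with an adjusted p of 0.81 with an estimated correlation and without mutant replicate 1 (0.0808). It was also lost without a filter (0.096), with a filter of 5 FPKM (0.0913) and with library weights (0.0643). Fry, which was not repeated under the alternatives, gave an adjusted p of 0.029 as down. Of 25 autophagy genes the lysosomal proteases cathD rose (0.57) and Cp1 fell (-0.47). Adjusted over the list alone 0 were called, with 1 higher and 7 lower at an unadjusted p under 0.05 (limma), and camera gave an adjusted p of 0.24. cathD lost its call without any 1 library other than control replicate 3 (0.0819 to 0.153), and Cp1 without mutant replicate 1 or 3 or control replicate 1 or 2 (0.118 to 0.187). Cp1 also lost it with both other scalings (0.0898 and 0.0622), and without control replicate 3 the list had 5 lower and 1 higher.

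**Figure D2:**
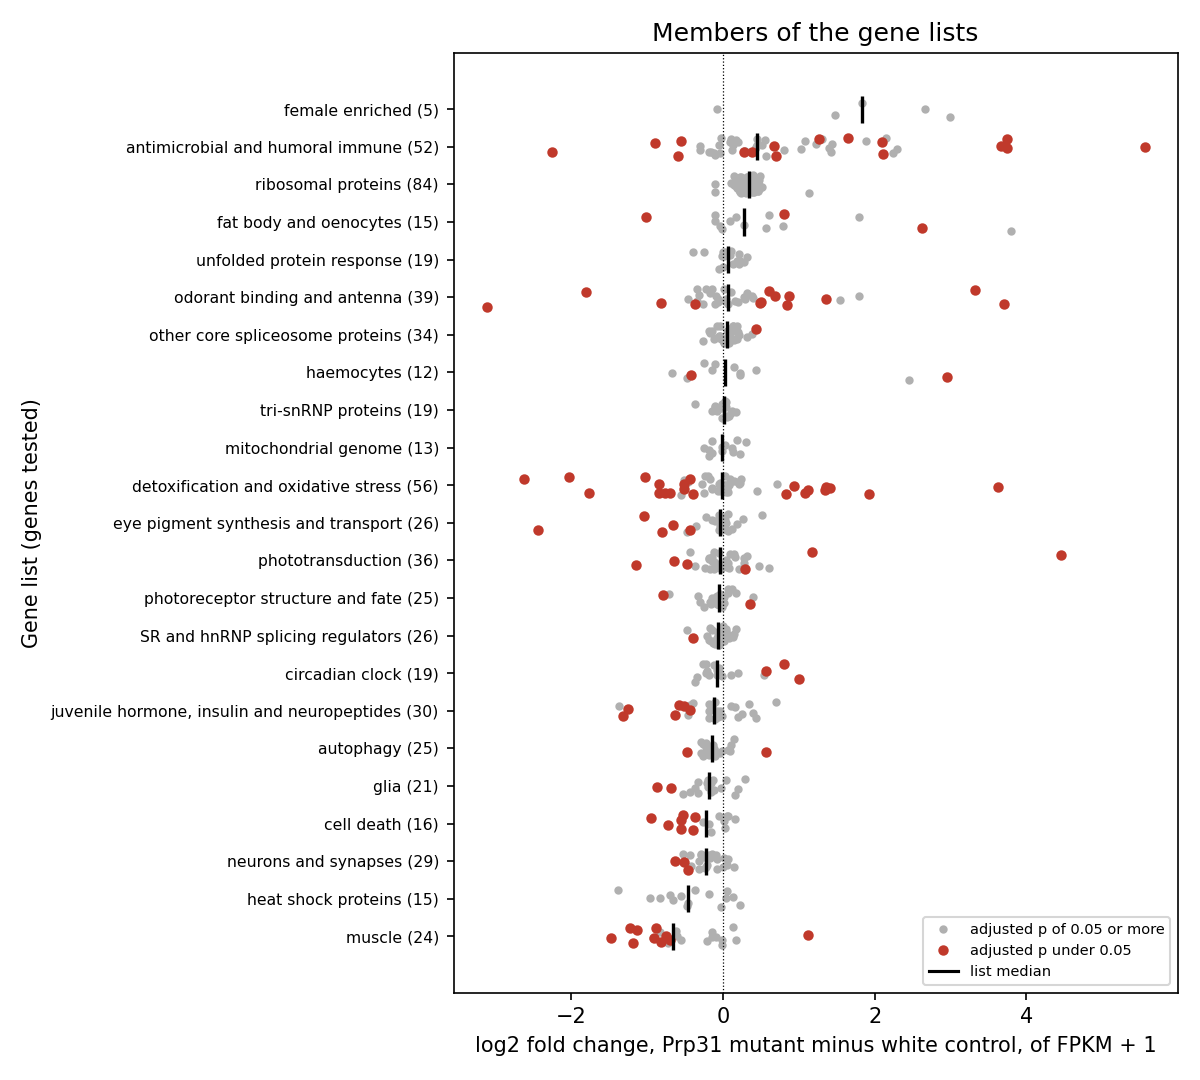
Log2 fold change of FPKM + 1, mutant minus control (horizontal axis), of each tested member (points) of 23 gene lists, ordered by their medians (black bars), with the number of genes tested after each name. Red points passed an adjusted p of 0.05 over all genes, such as 12 higher and 4 lower immune genes and 7 lower cell death genes.

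Neuropeptide transcripts were among those that fell. Of 30 genes of juvenile hormone, insulin and neuropeptides 6 fell and 0 rose, 7 and 0 when adjusted over the list alone, with 8 lower and 2 higher at an unadjusted p under 0.05 (limma). SIFa fell from 45.2 ± 9.44 to 17.2 ± 1.24 FPKM (log2 fold change -1.32, SE 0.15, limma adjusted p = 0.00221). The insulin-like peptide gene Ilp3 fell from 25.7 ± 3.92 to 10.2 ± 0.962 FPKM (-1.25, SE 0.12, limma adjusted p = 0.00095). Dh31 (-0.63) and Tk (-0.58) fell too, the latter losing its call without mutant replicate 3 (0.0534) or control replicate 2 (0.0547). Camera did not call the list (adjusted p = 0.24), and without control replicate 3 it had 7 lower and 5 higher, without mutant replicate 3 or control replicate 2 only 4 lower. Dh31 shares 1415 bases with Bace on the same strand. Of 19 circadian genes 3 rose and 0 fell, also when adjusted over the list alone, with 4 higher and 3 lower at an unadjusted p under 0.05. They were the clock neuropeptide gene Pdf (85.35 ± 7.19 against 42.0 ± 1.56 FPKM, log2 fold change 1.00, SE 0.09, limma adjusted p = 0.000616), to (0.81) and the transcription factor gene Clk (0.57). The calls of to and Clk were lost without control replicate 1 (adjusted p = 0.0563 and 0.0503), that of to also without mutant replicate 1 (0.0615), and camera gave the list an adjusted p of 0.35 (median -0.08, mean 0.05). Without control replicate 3, 5 were higher and 1 lower, and without control replicate 1 only Pdf was higher. Of 39 odorant binding protein and antennal genes 9 rose and 4 fell, 11 and 6 when adjusted over the list alone, led by Obp57a (3.70), Obp56a (3.32), Obp99d (-3.12) and Obp83g (-1.81). Camera called this list as up (adjusted p = 0.007, median 0.06), lost with an adjusted p of 0.81 with an estimated correlation and with quantile normalization (0.0715). Without any 1 library other than control replicate 3 the odorant list had 4 or 5 higher and 3 lower, and without that library 15 higher and 7 lower.

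Part of the muscle genes fell in mutant heads. Of 24 tested, 9 fell and 1 rose; adjusted over the list alone 14 fell and 1 rose. Act57B had 508, 702 and 508 FPKM in mutants and 1630, 1520 and 874 FPKM in controls, the last in control replicate 3. TpnC41C (-1.48) and the flight muscle actin gene Act88F (-1.23) had the largest decreases, followed by Act57B (-1.19) and the myosin light chain gene Mlc2 (-1.13). The calls of Act57B and Mlc2 were lost without any 1 library other than control replicate 3 (limma adjusted p 0.0503 to 0.151). Camera called the list as down (adjusted p = 0.0076, median -0.66), lost with an adjusted p of 0.85 with an estimated correlation and without mutant replicate 1 (0.0528). In this list control replicate 3 differed from control replicates 1 and 2 by a median of -0.60, the mutants differed from control replicate 3 by a median of -0.09, and without that library 16 members fell. With the yolk protein transcripts as a covariate the median of the list was -0.08, and 3 members fell. Without mutant replicates 1, 2 and 3 and control replicates 1 and 2 the numbers were 2, 5, 2, 3 and 2, with median-ratio scaling 3 and with quantile normalization 6. Of 29 neuronal genes Gad1 (-0.64), Vmat (-0.51) and SerT (-0.46) fell and 0 rose, also when adjusted over the list alone, with 10 lower and 0 higher at an unadjusted p under 0.05 (limma). Each of these 3 calls was lost without at least 4 of the libraries taken 1 at a time, with adjusted p up to 0.158, 0.139 and 0.134. Gad1 lost its call without mutant replicate 2 or 3 or control replicate 1 or 2, and Vmat and SerT without any library other than control replicate 3. Camera gave the neuronal list an adjusted p of 0.0501, not under the threshold, 0.0284 with median-ratio scaling and 0.0469 with quantile normalization, under both of which limma called 0 members. With an estimated correlation the adjusted p was 0.85. Without mutant replicate 1, control replicate 1 and control replicate 3 camera at its preset correlation gave 0.000367, 0.0174 and 0.0259, and without control replicate 3 limma called 9 members as lower. Of 21 glial genes Mdr65 (-0.87) and the astrocyte gene alrm (-0.69) fell and 0 rose, 3 and 0 when adjusted over the list alone, with 7 lower and 1 higher at an unadjusted p under 0.05 (limma). alrm lost its call without any 1 library other than control replicate 3 (0.053 to 0.0712), and alrm shares 1717 bases with Fur1 on the same strand. Camera gave the glial list an adjusted p of 0.15, 0.85 with an estimated correlation, and 0.00528 without control replicate 3, when 11 members were lower and 1 higher.

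Transcripts of the yolk proteins and of some genes of the fat body differed several-fold between libraries of 1 group. Yp1 had 9449, 8015 and 19772 FPKM in the mutants and 1817, 2044 and 8987 FPKM in the controls, and Yp3 had 6792, 5781 and 14725 against 606, 621 and 6084 FPKM. The female-enriched gene fit had 446, 369 and 1154 against 21.4, 23.0 and 701 FPKM, and the larval serum protein gene Lsp2 had 72.7, 61.3 and 451 against 3.27, 1.92 and 60.8 FPKM. None of 5 female-enriched genes was called by limma, also when adjusted over the list alone, although 4 were higher at an unadjusted p under 0.05, and 4 passed without control replicate 3. Camera called them as up (adjusted p = 0.028, median 1.83), lost with an adjusted p of 0.81 with an estimated correlation, without mutant replicate 3 (0.0744) or control replicate 1 (0.0553), and under both other scalings (0.0908 and 0.0764). Of the 2 male-enriched genes tested, to rose, also when adjusted over the list alone, and Cyp4d21 had 43.9, 53.9 and 15.4 against 43.6, 54.9 and 44.5 FPKM. Of 15 fat body and oenocyte genes Adh (2.63) and to (0.81) rose and Lsp1gamma (-1.02) fell, also when adjusted over the list alone. Adh had 6.83 FPKM in mutants and 0.252 FPKM in controls, near the floor, and shares 3351 bases with Adhr on the same strand. The call of Lsp1gamma was lost without mutant replicate 1 or 2 or control replicate 2 (0.0555 to 0.0857), and without control replicate 3 the list had 9 higher and 1 lower. Camera called it as up (adjusted p = 0.007, median 0.28), lost with an adjusted p of 0.81 with an estimated correlation. Control replicate 3 lay above control replicates 1 and 2 by a median of 0.63 and the mutants differed from control replicate 3 by -0.26. With the yolk protein transcripts as a covariate the median of the fat body list was -0.25 and that of the female-enriched genes -0.04. Yp1, Yp2 and Yp3 make up the covariate and are among these female-enriched genes, so the latter median was largely set by the covariate itself.

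Markers of blood cells, gut and gonads were tested as signs of other tissues in the samples. Of 12 haemocyte genes the prophenoloxidase gene PPO1 rose (2.95) and Hml fell (-0.42), 2 and 3 when adjusted over the list alone, and camera gave an adjusted p of 0.48. PPO1 had 36.7, 33.0 and 49.3 FPKM in mutants against 1.84, 1.66 and 17.4 FPKM, and its call was lost without any 1 library other than control replicate 3 (0.0715 to 0.125). Hml lost its call without mutant replicate 2 or 3 or control replicate 1 (0.0736 to 0.084), and without control replicate 3 the list had 5 higher and 4 lower. Of 4 gut genes Amy-d rose (1.13), 2 when adjusted over the list alone; it shares sequence with Amy-p, so their division is uncertain. Of 3 genes of ovary, germline and chorion Cp19 fell (-2.11), also when adjusted over the list alone. No testis gene reached the filter. None of 84 ribosomal protein genes was called by limma, also when adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05. Camera called them as up (adjusted p = 1.8e-14, median 0.34), lost with an adjusted p of 0.85 with an estimated correlation. Here control replicate 3 lay 0.66 above the other controls and the mutants lay -0.12 from control replicate 3, and without that library 80 of the 84 were higher. With the yolk protein transcripts as a covariate camera called this list as down instead (adjusted p = 0.0122, median -0.13). None of 13 mitochondrial genome transcripts was called by limma, also when adjusted over the list alone, nor at an unadjusted p under 0.05, and camera gave an adjusted p of 0.33.

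**Figure D3:**
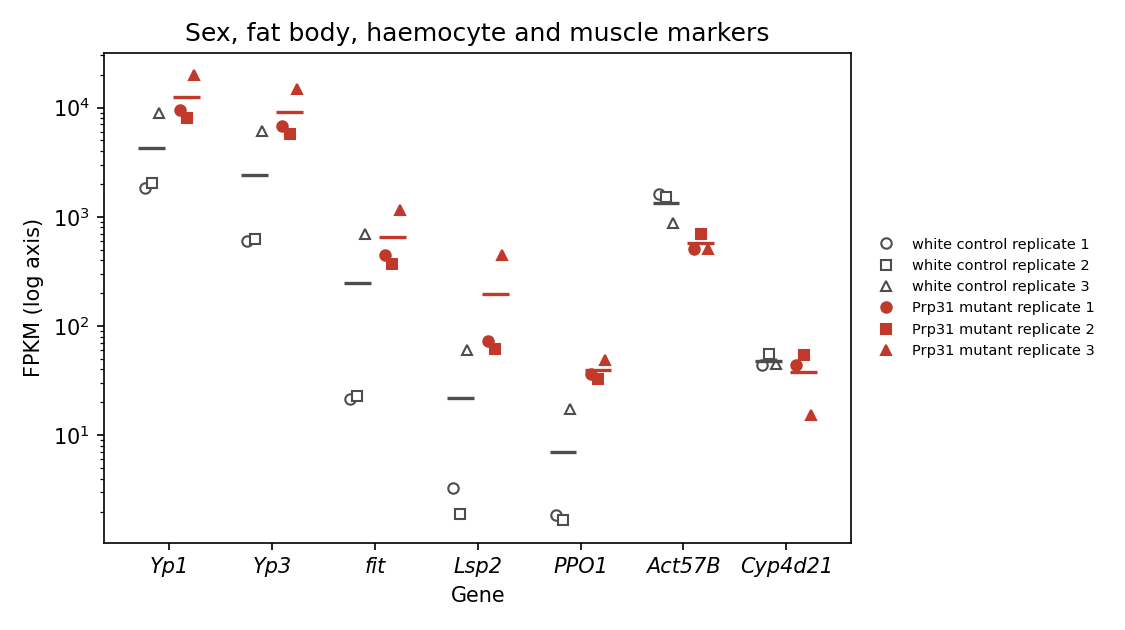
FPKM (log axis) of markers of females (Yp1, Yp3, fit), fat body (Lsp2), haemocytes (PPO1), muscle (Act57B) and males (Cyp4d21) in each library, with control libraries as open grey and mutant libraries as filled red symbols and bars at the group means. White control replicate 3 lies near the mutants for Yp1, at 8987 FPKM, while control replicates 1 and 2 lie at 1817 and 2044 FPKM.

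Called genes were not spread evenly over the chromosome arms. On 3R 301 of 2114 tested genes were called (14.2%, odds ratio 1.44, 95% interval 1.24 to 1.67, Fisher's exact test, two-sided, adjusted p = 5.6e-06). On 3L 214 of 1611 were called (13.3%, odds ratio 1.26, 95% interval 1.06 to 1.48, adjusted p = 0.013). On X 101 of 1378 were called (7.33%, odds ratio 0.574, 95% interval 0.458 to 0.712, adjusted p = 6.3e-07) and on 2L 139 of 1481 (9.39%, odds ratio 0.778, adjusted p = 0.013). On 2R the odds ratio was 0.961 (adjusted p = 0.67) and on chromosome 4 it was 0.565 (adjusted p = 0.32). Within 2 Mb of Prp31 38 of 256 genes were called, an odds ratio of 1.17 against the rest of 3L (95% interval 0.777 to 1.72, Fisher's exact test, two-sided, p = 0.42). The called genes there include st, CG4962 and Rh4, for which an allele linked to Prp31 cannot be told apart from the mutation. Genes are not independent replicates, so these intervals describe these lists of genes. Without control replicate 3 the odds ratios of 3R and 3L were 1.13 and 1.12 and lost their calls (adjusted p = 0.083 and 0.118). In the same exact test, the call of 3L was also lost without mutant replicate 2 (1.13, adjusted p = 0.278) or 3 (1.27, 0.056) or control replicate 1 (1.25, 0.107). The 2 Mb around Prp31 passed the exact test without mutant replicate 1 (odds ratio 1.66, p = 0.0302) or 3 (1.64, 0.0362) or control replicate 1 (1.70, 0.0407) or 2 (1.62, 0.0494).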

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

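The yolk protein covariate was chosen after seeing the data; the other alternatives here were set earlier. Prp31 did not pass under any of the 17 alternatives (log2 fold change -0.04 to 0.05, limma adjusted p 0.612 to 0.959). Of 103 named genes 64 were called and 36 of these were called under every alternative, and 0 of the called genes changed sign. Some genes that were not called did, as with the yolk protein covariate fit (2.99 to -0.58) and Hsp83 (-0.55 to 0.12). Yp2 did too (1.48 to -0.21), but it is part of the covariate. That covariate ended 23 calls, and those of ninaD, Dark, Amy-d, Obp83g and Dh31 were lost under no other alternative. The odds ratio on X stayed past its threshold under every alternative.

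The 299 genes higher and 661 lower became 1128 and 2170 with library weights and 181 and 310 with the yolk protein covariate, which called 371 of the 960 genes again in the same direction. With each library left out they ranged from 144 to 838 and from 268 to 1383, with the lowest counts without white control replicate 1 and the highest without white control replicate 3. A filter of 5 FPKM tested 6145 genes and gave 417 lower. At least 2-fold changed 243 genes, 160 with that filter, and 186 (without mutant replicate 1) to 369 (without white control replicate 3) with a library left out. Apart from the filter, which tested fewer genes, the cause was not tested.

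Of 25 lists 9 were called, 7 to 14 with a library left out (14 without white control replicate 3). Camera with an estimated correlation called 0, also at an unadjusted p under 0.05, and fry 2. With the yolk protein covariate the ribosomal list turned from up to down and was called (median 0.34 to -0.13), and the heat shock list, not called before, was called as up (-0.46 to 0.41). The median of the fat body list went from 0.28 to -0.25, that of the female-enriched genes from 1.83 to -0.04, those of the other spliceosome and unfolded protein response lists from 0.05 and 0.06 to -0.05 and -0.01, and that of muscle from -0.66 to -0.08, and none of these 5 was called. The cell death list was not called either (adjusted p = 0.103), although its median stayed at -0.20 from -0.22. The female-enriched list holds the yolk protein genes that make up the covariate, so its median there was largely set by the covariate. The phototransduction, photoreceptor and mitochondrial lists were newly called as up, as were the genes with 10 or more introns, down before without a call, and the neuropeptide list as down. Members that rose and fell went from 9 and 4 to 6 and 2 among odorant genes, from 0 and 3 to 0 and 0 among neuronal genes, from 0 and 7 to 0 and 2 among cell death genes, and from 10 and 27 to 5 and 5 among genes with 10 or more introns.

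The odds ratio on 3L of 1.26 lost its call without a filter (1.16), with library weights (1.12), with the block (1.15, adjusted p = 0.117) and with the yolk protein covariate (1.26, adjusted p = 0.0879), and ranged from 1.12 to 1.36 (1.119 to 1.355) with a library left out. On 3R it was 1.44, lost its call with library weights (1.04), and ranged from 1.134 to 1.597. Within 2 Mb of Prp31 it passed Fisher's exact test with the yolk protein covariate (1.88, p = 0.00987) and ranged from 0.854 to 1.70 with a library left out; windows of 1 and 5 Mb gave 0.928 and 0.950. The cause was not tested.

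The replicate number as a block gave 406 genes higher and 736 lower, with 883 of the 960 called again, and 10 lists. Yp2 (adjusted p = 0.0294), Yp3 (0.0254), fit (0.0412) and Lsp2 (0.00143) passed limma's test with it. Deviations of libraries with the same number correlated at -0.011, 0.21 and 0.318 (across genes, which are not independent replicates), and mutant replicate 2 correlated best with control replicate 1 (0.31), so the numbers were not read as pairs. Exact depths are not known, and low values were given no counting error.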

Other observations

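All tests in this part were chosen after the result was seen, except the count of lists under other splits of the libraries.

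Among 31 families of at least 8 tested genes that share a symbol prefix, the cuticle protein genes named Cpr had the strongest excess of decreases. Of 27 tested, 14 fell and 0 rose (Fisher's exact test, one-sided, adjusted p = 1.3e-07), with Cpr51A at -1.12 and Cpr49Aa at -1.40. The number that fell was 6, 13 and 6 without mutant replicates 1, 2 and 3, 4, 6 and 18 without control replicates 1, 2 and 3, and 12 and 14 under the other scalings. Under the yolk protein covariate 3 fell and 2 rose. Genes named Cyp, mostly cytochrome P450s and including a cyclophilin, were in excess among increases (13 of 64, adjusted p = 8.3e-06) and decreases (15 of 64, adjusted p = 0.0014). The increases numbered 13, 12 and 11 without mutant replicates 1, 2 and 3 and 10, 10 and 21 without control replicates 1, 2 and 3, and 8 with the yolk protein covariate. The decreases numbered 10, 12 and 11, then 9, 10 and 16, and 14, and 10 with median-ratio scaling. Obp genes were in excess among increases (8 of 31, adjusted p = 0.00018), with 5, 4 and 4 without mutant replicates 1, 2 and 3, 3, 3 and 14 without control replicates 1, 2 and 3, and 4 with the yolk protein covariate. Genes are not independent replicates.

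The eye colour genes cn and w lay under the filter. cn had 1.04, 0.852 and 0.47 FPKM in mutant and 0.019, 0.019 and 0.017 FPKM in control libraries, and w had 0.284, 0.373 and 0.524 against 0.023, 0.015 and 0.046 FPKM. Desat2 had 7.52, 3.37 and 20.5 against 0.109, 0.345 and 0.193 FPKM. In white control replicate 2, 211 genes were above 0 that were at 0 in the other 5 libraries, none above 2.08 FPKM, and 13 of 15 testis genes were highest there, such as Mst84Dc at 1.63 FPKM.

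Yolk protein transcripts in white control replicate 3 lay near those of the mutants, and mutant replicate 3 held more of them than the other mutants (Yp1 by 1.18 in log2). In control replicate 3 log2(Yp1/Yp3) differed by -1.09 from the other controls, which argues against a different share of otherwise equal females as the whole cause. The argument from these ratios rests on Yp3, as log2(Yp1/Yp2) differed by 0.41, within the bound of 0.5. The male-enriched gene Cyp4d21 lay within the range of the other controls there (44.5 against 43.6 and 54.9 FPKM). Cuticle genes were lower there than in the other controls by a median of -0.51 (27 of 34 genes), so control replicates 1 and 2 may come from less mature adults. The bound for this was set with the values known, the labels give 2 days for all, and feeding or handling was not tested. The mutants lay below control replicates 1 and 2 in these genes by a median of -0.85, with 16 called lower and 1 higher in mutants. The decreases of cuticle genes in mutants thus cannot be told apart from a difference in maturity. In mutant replicate 3 the same ratios differed by -0.05 and -0.45, the male-enriched genes Cyp4d21 and to by -1.60 and -0.51, and the cuticle genes by -0.01, so a larger share of females in that pool is a candidate explanation. It leaves open Lsp2, which was higher there by 2.74.

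Calls were more frequent on the third chromosome, which carries Prp31 (515 of 3725 genes, 13.8% against 9.34% elsewhere, odds ratio 1.56, 95% interval 1.36 to 1.79). The odds ratio was 1.58 without the genes within 5 Mb of Prp31, which argues against a segment there as the whole cause, and 1.64 with the yolk protein covariate, which argues against the yolk protein state as that covariate measures it. Without white control replicate 3 it was 1.18 (1.07 to 1.31). That fit called 2221 genes instead of 960, so the 2 odds ratios are not directly comparable. A chromosome 3 of other origin in the mutant stock could raise calls on both arms and stays open, as the smallest odds ratio of an arm, on 3L without that library, was 1.12 with an interval of 0.989 to 1.27. The labels do not give the background of either stock, and any difference in it cannot be told apart from the mutation.

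Rh6 rose by a log2 fold change 3.99 larger than that of ninaE, which argues against reads shared with that opsin. The other 35 phototransduction genes had a median of -0.05 (quartiles -0.16 and 0.15), which argues against more eye tissue in the mutant libraries. A difference in Rh6 itself may remain, in the number of cells or in the level per cell. It may come from the Prp31 mutation or from a difference in strain background, which was not tested. Rh6 lay below Rh5 in controls (21.6 against 261 FPKM) and above it in mutants (504 against 194 FPKM). Whether the control level is low or the mutant level raised cannot be told from these groups.

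The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 960 called genes, 299 higher, 661 lower and 243 changed at least 2-fold. The highest of the other splits gave 0 of each (limma, with 28 to 1041 genes at an unadjusted p under 0.05), so 1 of the 10 splits reached the real count in each case. Every other split put mutant and control libraries in both groups, so their difference widened the spread within groups. Low counts there follow from this design, and no conclusion is drawn from them. For lists 5 of the 10 splits gave as many as the real 9, the highest 17 with mutant replicate 1 and control replicates 1 and 2 against the rest, then 13 with mutant replicates 1 and 3 and control replicate 3. Camera at its preset correlation of 0.01 may call correlated lists too readily, as 0 lists were called with an estimated correlation, which reached 0.95 for ribosomal proteins. This was not separated from a structure of the samples.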
